A study of Homo sapiens with 22 samples.

How the data were processed

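RNA was measured in peripheral blood mononuclear cells of 11 donors with atopic dermatitis (AD), each given HSV-1 at a multiplicity of infection of 0.1 or sham for 21 h, in 22 libraries. Per the labels' protocols, poly-A TruSeq RNA libraries were sequenced on a HiSeq instrument. The submitters' processing notes name CASAVA 1.8.2, Bowtie, TopHat, Partek 6.6 and the genome build hg19, without the role of each. The gene annotation and the settings are not given in the sources used here. The deposited table holds normalized values that were taken as RPKM, a unit that no header or label states. The libraries sum to different totals over the genes listed, and low values of single-exon interferon genes are whole multiples of a step that is inversely proportional to gene length, as reads divided by gene length and library size are. Every one of the 8716 genes in the deposited table reaches 5 RPKM in at least 5 of the 22 libraries (smallest fifth-highest value 5.0004), a filter seen in the values. Genes silent in these cells are therefore not in the table, and the interferon genes IL28A, IL28B and IFNE were not analysed here. The table has 120 zeros, and 15 symbols appear as dates. Each library column was matched to its sample by the AD type, treatment and replicate number in its name, and no column was left unused.

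The depth of each library was estimated from the steps between low values of 6 single-exon interferon genes. Their lengths were taken from these steps relative to the reference length of IFNA21, and they equal the reference gene table for IFNA10 and IFNA16 and differ from it for IFNA1 (876 against 878 bases), IFNA2 (1143 against 1144) and IFNB1 (840 against 839). With these lengths the values came out as whole read numbers within 0.0097 reads at the estimated depth in all 22 libraries, a check that is partly fitted to the values it tests. No count test was run, since read counts of the other genes were not recovered. Depth did not differ between the AD types beyond the spread of donors after HSV-1 (two-sided exact permutation test, p = 0.58) or sham (p = 0.874). Coordinates are not given, since the reference used here is of another genome build than hg19.

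From the deposited values, 11 genes of X-inactivation or with Y-chromosome copies were left out of every table and total, which left 8705 genes. Values were analysed as log2(RPKM + 0.5) without further scaling, in genes with at least 1 RPKM in at least 5 libraries of the fit. limma 3.58.1 (R 4.3.3) with an intensity trend and Benjamini-Hochberg adjustment at 0.05 gave the tests. The 2 responses to HSV-1 and their difference came from 1 fit of 22 libraries with the donor as a block, since the series' design text says that the cells of each subject were divided. In this fit the 11 donors' HSV-1 and sham libraries deviated together from their group means (correlation 0.296 to 0.754), and in 11 of 11 donors the HSV-1 library correlated best with the donor's own sham library. The AD types were compared within the 11 libraries of each treatment without a block, because replicate numbers name different subjects in the 2 AD types.

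Gene lists (42 of pathways and cell types) were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Lists with fewer than 3 measured members were not tested, which left 40 lists in the fits of 22 libraries and 39 in each comparison of AD types. The tests, covariates, gene lists, the rule for named genes and the alternatives, except those marked as added later, were chosen before the data were examined. The rule named, per comparison, up to 12 genes with the largest rise and 12 with the largest fall among genes past the threshold, with a mean of at least 5 RPKM in the higher group and, for responses, the same direction in every donor. Where fewer than 10 passed, genes of smallest p were added up to 10. From each list described, members of smallest p were named, and IFNG, IRF3, IRF7, CXCL10 and the interferon genes were always followed. Some genes that the rule covers are not reported here. Small RNA and uncharacterized symbols were not named, nor were genes whose level can follow a donor's genotype. Of the genes the rule named, those printed were chosen for their known function. The mean log2 value of each list's members per donor was compared between AD types with two-sided exact permutation tests over 462 splits of the donors, whose smallest possible p is 0.00216.

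Alternatives covered the pseudocount (0.1 and 1), the filter (none, or 5 RPKM in 5 libraries), the scaling (TMM with trims of 30% and 5%, coded for these values, quantile normalization and one median per library), robust limma, array weights, the donor or replicate block, fits of one AD type alone, the donor as a random effect, a fold change of at least 2 and leaving out each donor in turn. The median scaling, and for the lists also TMM, quantile normalization and the fit without the block, and for the donors' means leaving out each donor, and leaving out ADEH− replicates 2, 4 and 6 together, were added after seeing the data.

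The tests were tried on simulated data with known changes for the real genes. In the ADEH− response (8705 genes) 82.1% of genes with a log2 change of 0.5 were recovered, 89.6% at 1 and 100% at 2. In the ADEH+ response (8705 genes) the shares were 71.6%, 91% and 98.5%, and for the difference of responses (8705 genes) 47.8%, 88.1% and 95.5%. Between AD types they were 47.8%, 91% and 97% after HSV-1 (8669 genes) and 50.7%, 79.1% and 98.5% after sham (8638 genes). Of 3 lists given a shift in the simulated ADEH− response, camera called 3, and of 32 lists without a shifted gene it called 0. The simulated genes varied independently, unlike the members of most real lists. The 0 calls therefore do not show how often camera calls a real list falsely. Scripts ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.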

Results

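Gene expression was measured by RNA sequencing in peripheral blood mononuclear cells, the unsorted mixture of lymphocytes, monocytes and rarer dendritic cells of blood. The cells came from 11 donors with atopic dermatitis, a chronic allergic inflammation of the skin. Of these, 5 had a history of eczema herpeticum, a herpes simplex virus infection that spreads across the skin (ADEH+), and 6 had no such history (ADEH−). The cells of each donor were divided, and one part was given herpes simplex virus 1 (HSV-1) at a multiplicity of infection of 0.1 and the other a sham treatment for 21 h. This gave 22 libraries, with 6 ADEH− and 5 ADEH+ libraries per treatment. The deposited table held 8716 human gene symbols with their RPKM (reads normalized to gene model length and library size), and viral transcripts were not analysed here. The low values gave a depth of 25.2 to 68.3 M (mega) reads per library. The mean depth was 48.4 ± 10.9 M reads (SD, n = 6) in ADEH− and 51.7 ± 12.6 M (SD, n = 5) in ADEH+ cells after HSV-1. After sham it was 43.7 ± 13.4 M (SD, n = 6) in ADEH− and 44.9 ± 10.1 M (SD, n = 5) in ADEH+ cells. Mean levels are given as RPKM ± SD over the donors of a group, and changes as log2 values ± SE on the log2(RPKM + 0.5) scale, which understates the change of genes with low levels. The p-values of limma and of the exact permutation tests measure the spread between donors. Those of camera at its preset correlation compare a list's members with other genes, and do not measure how a list varies between donors.

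The first principal component held 70.9% of the variance and parted all HSV-1 from all sham libraries, and the second held 7.7%. Libraries of one group correlated with each other at Pearson's r of 0.912 to 0.982 across genes, which are not independent replicates.

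**Figure D1:**
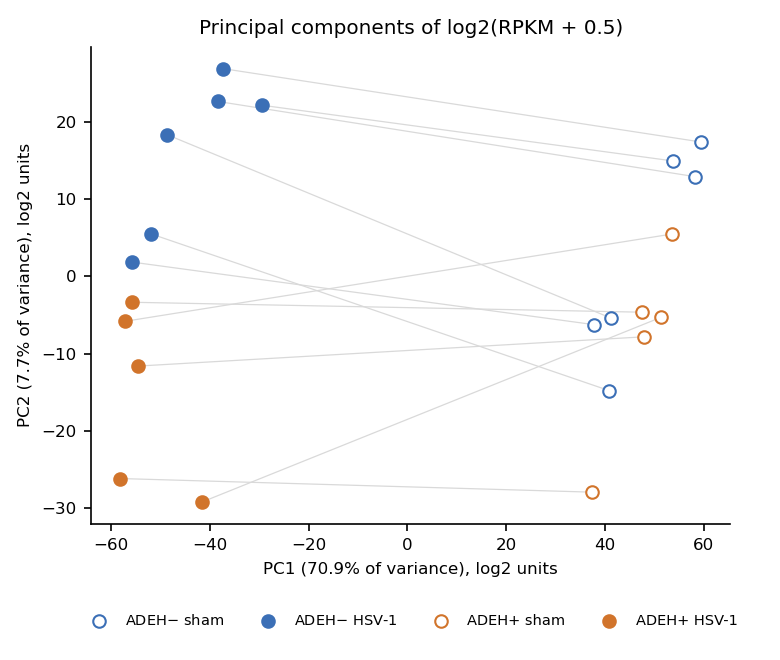
Principal components of log2(RPKM + 0.5) over 8705 genes. Each point is 1 library, filled for HSV-1 and open for sham, coloured by AD type, and grey lines join the libraries of a donor. The horizontal axis, with 70.9% of the variance, parts the 11 HSV-1 libraries on the left from the 11 sham libraries on the right.

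The first comparison asked which genes HSV-1 changed in cells of ADEH− donors. Interferon genes, interferon-stimulated genes and most chemokines rose steeply, while ribosomal protein genes and most T cell markers fell. IFNB1, which encodes the type I interferon beta, stood at 87.4 ± 41 RPKM (SD, n = 6) after HSV-1 and at 0.109 ± 0.0545 RPKM after sham. CXCL10, a chemokine that attracts activated T cells, reached 5485 ± 2147 RPKM (SD, n = 6) against 76 ± 76.2 after sham. CD14, the lipopolysaccharide co-receptor of monocytes, dropped from 100.5 ± 30.7 to 6.56 ± 3.92 RPKM (SD, n = 6). Each of these changes went the same way in 6 of 6 donors.

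All 42 measured type I interferon-stimulated genes rose in ADEH− cells, with a median log2 change of 4.13 (camera, adjusted p = 6.96e-34; adjusted p = 0.0615 with an estimated correlation). RSAD2, which encodes the antiviral enzyme viperin, rose by 7.41 ± 0.17, and IFIT1, which binds viral RNA, by 7.46 ± 0.25. USP18, a brake on interferon signalling, rose by 6.25 ± 0.11 and the interferon-inducible gene IFI27 by 7.56 ± 0.50. All 16 measured type I and III interferon genes also rose, with a median of 5.87 (camera, adjusted p = 1.3e-12; adjusted p = 0.169 with an estimated correlation). These 16 genes lay near 0 after sham. They could pass the deposited table's filter of 5 RPKM in at least 5 libraries only through HSV-1 libraries, so their rise was largely set in advance. IFNA2 reached 47 ± 23.5 RPKM (SD, n = 6), IFNW1 29.9 ± 14.8 and IL29, which encodes the type III interferon lambda 1, 30.6 ± 14.9. The interferon alpha genes are near-identical in sequence and can share reads, so the values of single members are uncertain. Among nucleic acid sensors and their adaptors 17 of 23 rose and 3 fell, at a median of 1.28 (camera, adjusted p = 4.56e-08; adjusted p = 0.0937 with an estimated correlation). The RNA sensors DDX58 (RIG-I) and IFIH1 (MDA5) rose by 3.73 ± 0.05 and 4.05 ± 0.15. Among interferon receptors, JAK, STAT and IRF factors 16 of 22 rose and 4 fell (camera, adjusted p = 3.75e-06; adjusted p = 0.118 with an estimated correlation). In this list IRF7, a transcription factor that amplifies interferon production, rose by 3.82 ± 0.12, while IRF3, a constitutive factor upstream of IFNB1, fell by 0.39 ± 0.07. Antiviral restriction factors rose in 25 of 28 cases at a median of 1.8, and APOBEC3A, a cytidine deaminase, reached 805 ± 241 RPKM (SD, n = 6). That list passed camera with a preset (adjusted p = 3.65e-17) and an estimated correlation (adjusted p = 0.0159).

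Of the type II interferon-responsive genes 21 of 23 rose in ADEH− cells and none fell, with a median log2 change of 2.95 (camera, adjusted p = 9.97e-14; adjusted p = 0.134 with an estimated correlation). IFNG, the type II interferon gene of T and NK cells, rose by 2.24 ± 0.59 (limma, adjusted p = 0.00448). Chemokines rose in 12 of 18 cases and fell in 3, with a median of 3.43 (camera, adjusted p = 1.05e-05; adjusted p = 0.0327 with an estimated correlation). CXCL11 and CCL8, which attract T cells and monocytes, rose by 8.04 ± 0.25 and 7.95 ± 0.25, and CCL7 by 6.70 ± 0.58. In the sham libraries alone 15 chemokines and 21 type II interferon-responsive genes reached 1 RPKM in at least 5 libraries. The other members of both lists could enter the deposited table only with HSV-1 libraries, so their rise was partly set in advance. This can raise the share and median of both lists. NF-kappaB target genes rose in 23 of 24 cases (camera, adjusted p = 1.5e-11; adjusted p = 0.0937 with an estimated correlation), among them the inhibitor NFKBIA by 1.63 ± 0.12. Anti-inflammatory and regulatory genes rose in 14 of 22 cases and fell in 3 (camera, adjusted p = 5.61e-06; adjusted p = 0.0159 with an estimated correlation). CD274, which encodes the checkpoint ligand PD-L1, rose by 3.96 ± 0.14, LAG3 by 3.70 ± 0.14 and IL1RN, the interleukin 1 receptor antagonist, by 6.80 ± 0.30. Apoptosis genes rose in 17 of 25 cases and fell in 5 (camera, adjusted p = 5.38e-07; adjusted p = 0.0149 with an estimated correlation), with the death ligand TNFSF10 (TRAIL) up by 4.41 ± 0.21 and the death receptor FAS by 2.59 ± 0.13.

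All 54 measured ribosomal protein genes fell in ADEH− cells, at a median of −0.89 (camera, adjusted p = 5.15e-11; adjusted p = 0.37 with an estimated correlation). RPL4 changed by −1.37 ± 0.08 and RPS16 by −1.03 ± 0.06. Of the T cell markers 23 of 29 fell and 3 rose, at a median of −0.71, which camera did not call (adjusted p = 0.0518), although it called the list under TMM (adjusted p = 0.0208), quantile (0.0019) and median scaling (0.0324; adjusted p = 0.734 with an estimated correlation and no further scaling). The co-receptor CD4 changed by −2.20 ± 0.16, the costimulatory receptor CD27 by −1.77 ± 0.15 and the T cell receptor kinase LCK by −1.17 ± 0.10. Of the monocyte and macrophage markers 16 of 29 fell and 5 rose (median −0.81; camera, adjusted p = 0.785). CD14 changed by −4.01 ± 0.39 and the lectin FCN1 by −2.77 ± 0.27, while the scavenger receptor MSR1 rose by 3.54 ± 0.25. NK cell markers fell in 9 of 15 cases and rose in 2 (camera, adjusted p = 0.65), and all 4 measured platelet and megakaryocyte markers fell, at a median of −1.58 (camera, adjusted p = 0.24). Among all genes the steepest falls that were shared by 6 of 6 donors included PID1 (−4.98 ± 0.24), the ribonucleases RNASE1 (−4.75 ± 0.37) and RNASE6 (−4.17 ± 0.20), the macrophage complement receptor VSIG4 (−4.28 ± 0.33), the coagulation factor subunit F13A1 (−4.27 ± 0.52) and the chemokine receptor CCR2 (−3.66 ± 0.40). FGFBP2, a secreted protein of cytotoxic lymphocytes, fell by 3.58 ± 0.17.

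In total 6494 of 8705 genes passed limma's test at an adjusted p under 0.05 in ADEH− cells, of which 1968 rose and 4526 fell. Of these, 1485 changed at least 2-fold, 709 up and 776 down. The median log2 change of all genes was −0.21 on the deposited scale and −0.02 after TMM scaling, under which 2999 genes rose and 3186 fell. With every library scaled to one median 2575 rose and 3660 fell, and with quantile normalization 2501 rose and 3752 fell. The list medians given above kept their sign under these 3 scalings.

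The second comparison asked the same of ADEH+ donors. In cells of ADEH+ donors interferon-stimulated genes and most chemokines rose, and ribosomal protein genes and most T cell markers fell. CXCL10 rose from 15.2 ± 2.78 to 7176 ± 2017 RPKM (SD, n = 5) and CCL8 from 1.4 ± 0.553 to 1570 ± 750. IFNB1 stood at 31 ± 12.6 RPKM (SD, n = 5) after HSV-1 and at 0.0978 ± 0.0225 after sham. IFNG stood at 59.7 ± 46.9 RPKM (SD, n = 5) after HSV-1 and at 0.551 ± 0.298 after sham. CD14 dropped from 188 ± 119 to 6.93 ± 3.07 RPKM (SD, n = 5). Each of these changes went the same way in 5 of 5 donors.

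All 42 type I interferon-stimulated genes rose in ADEH+ cells, at a median log2 change of 4.00 (camera, adjusted p = 1.24e-29; adjusted p = 0.0862 with an estimated correlation). RSAD2 rose by 7.43 ± 0.18 and IFIT1 by 6.95 ± 0.27. All 16 type I and III interferon genes rose, at a median of 4.30 (camera, adjusted p = 1.77e-09; adjusted p = 0.235 with an estimated correlation). As in ADEH− cells, the filter of the deposited table largely set the rise of these genes in advance. IFNA2 reached 14.7 ± 5.92 RPKM (SD, n = 5), IFNW1 9.86 ± 4.42 and IL29 10.4 ± 4.87, while IFNA4 and IFNA13 were listed at 0 in all 5 ADEH+ sham libraries. Of the type II interferon-responsive genes 22 of 23 rose, at a median of 3.85 (camera, adjusted p = 6.28e-15; adjusted p = 0.128 with an estimated correlation). In this comparison IRF7 rose by 3.77 ± 0.13 and IRF3 fell by 0.59 ± 0.07. Chemokines rose in 12 of 18 cases and fell in 3 (camera, adjusted p = 1.43e-05; adjusted p = 0.0416 with an estimated correlation), and anti-inflammatory and regulatory genes rose in 15 of 22 and fell in 3 (camera, adjusted p = 2.31e-06; adjusted p = 0.0186 with an estimated correlation). The filter limits the chemokines and type II interferon-responsive genes here as in ADEH− cells. CD274 rose by 5.46 ± 0.16. Antiviral restriction factors rose in 26 of 28 cases (camera, adjusted p = 2.28e-16; adjusted p = 0.0186 with an estimated correlation). MHC class II processing and presentation genes rose in 11 of 15 cases (camera, adjusted p = 0.000222; adjusted p = 0.206 with an estimated correlation), among them the costimulatory ligand CD80 by 5.55 ± 0.20 and CD40 by 3.59 ± 0.26. DEFB1, an antimicrobial defensin, rose by 6.48 ± 0.34, and ANKRD22 by 6.46 ± 0.28.

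All 54 ribosomal protein genes fell in ADEH+ cells, at a median of −1.17 (camera, adjusted p = 1.04e-11; adjusted p = 0.341 with an estimated correlation), among them RPS16 (−1.16 ± 0.06). Of the T cell markers 23 of 29 fell and 1 rose, at a median of −1.0 (camera, adjusted p = 0.00247; adjusted p = 0.526 with an estimated correlation). CD27 changed by −2.29 ± 0.16, CD5, a negative regulator of T cell receptor signalling, by −1.92 ± 0.11 and LCK by −1.68 ± 0.11. Of the monocyte and macrophage markers 15 of 29 fell and 8 rose, with a median of −0.75 and a camera test that pointed up and did not pass (adjusted p = 0.661). CD14 changed by −4.55 ± 0.43 and FCN1 by −2.81 ± 0.30, while MSR1 and the complement gene C1QB rose by 3.64 ± 0.28 and 3.52 ± 0.37. PID1 (−5.35 ± 0.27), F13A1 (−4.60 ± 0.57), VSIG4 (−4.38 ± 0.36) and the matrix proteoglycan VCAN (−4.14 ± 0.49) were among the steepest falls.

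In ADEH+ cells 6656 of 8705 genes passed limma's test at an adjusted p under 0.05, with 2115 higher and 4541 lower, and 2072 of them changed at least 2-fold, 827 up and 1245 down. The median log2 change of all genes was −0.25 on the deposited scale and 0.0042 after TMM scaling, under which 3270 genes rose and 3233 fell. With every library scaled to one median 2831 rose and 3714 fell, and with quantile normalization 2711 rose and 3736 fell. The list medians given for ADEH+ cells kept their sign under these 3 scalings. Across the 8705 genes the responses of both AD types, which rest on different donors, correlated with a Pearson's r of 0.954 and a Spearman's rho of 0.947. Of the 5946 genes that passed in both, 5936 moved the same way, 1757 up and 4179 down, where 478 and 2361 shared genes were the number for independent lists.

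**Figure D2:**
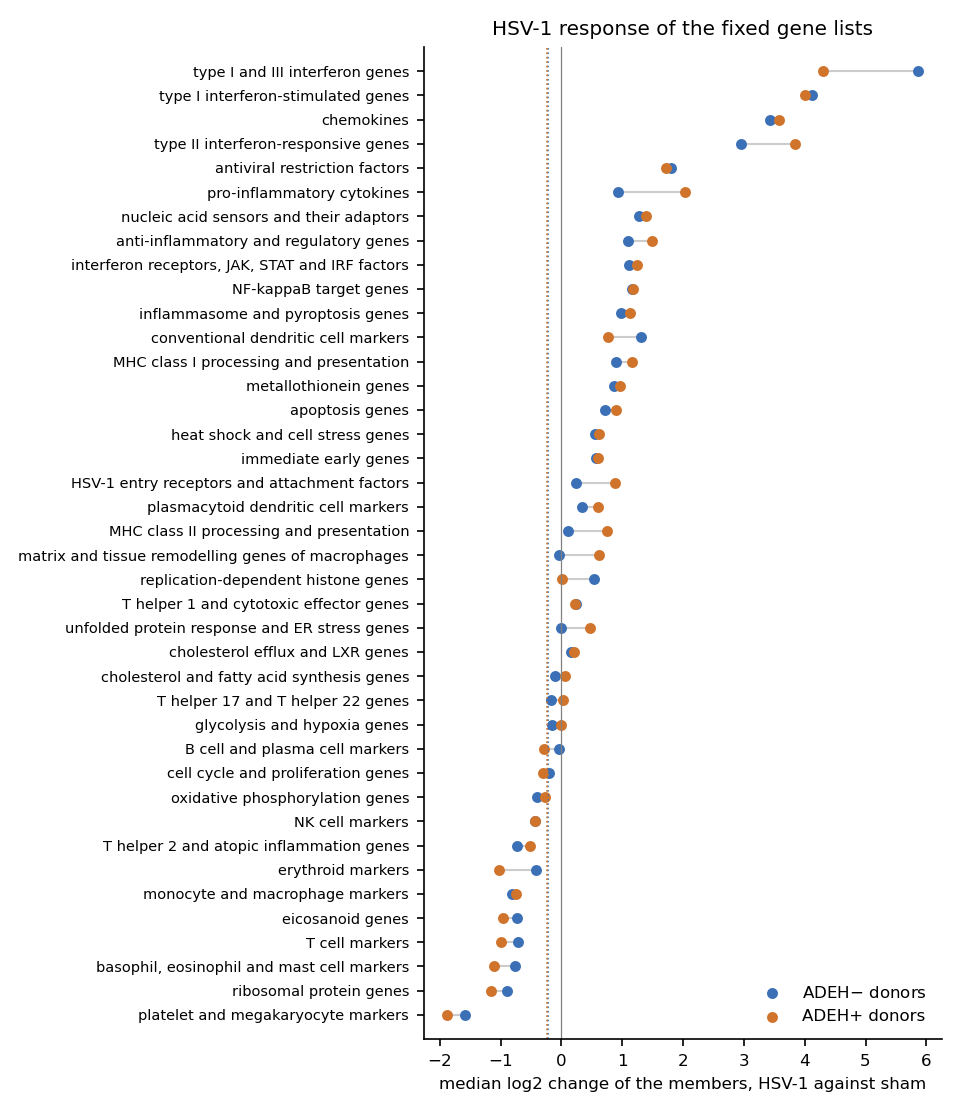
Median log2 change of the measured members of 40 gene lists, HSV-1 against sham, on the log2(RPKM + 0.5) scale, with 1 point per AD type. Dotted lines mark the median of all genes, −0.21 in ADEH− and −0.25 in ADEH+ donors. Interferon and interferon-stimulated genes lie at the top and ribosomal protein and platelet genes at the bottom in both AD types. Lists with medians near 0, such as B cell and plasma cell markers in ADEH− donors, can change sign with the scaling.

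The third comparison asked whether the cells of the AD types differed before infection, in the sham libraries. None of the 8638 genes tested passed limma's test (smallest adjusted p = 0.933), and 321 genes had an unadjusted p under 0.05 where 431.9 were the number for no difference at all. The genes of smallest p, given as not past the threshold, included SEMA4D, a semaphorin of T cells, with a difference of −0.47 ± 0.09 (ADEH+ minus ADEH−). The potassium channel gene KCNN4 lay at 0.90 ± 0.18, the decoy interleukin 1 receptor IL1R2 at 1.23 ± 0.28, the eosinophil-attracting chemokine CCL24 at 2.53 ± 0.59 and the antioxidant enzyme GPX3 at 1.27 ± 0.32. AVPI1 (1.03 ± 0.22), CALHM2 (0.44 ± 0.11), GDPD5 (0.57 ± 0.14) and SLC25A45 (−0.47 ± 0.12) complete the set, apart from 1 gene whose level can follow a donor's genotype and is not named. IRF3 stood at 60.8 ± 8.25 RPKM (SD, n = 5) in ADEH+ and 60.9 ± 6.32 (SD, n = 6) in ADEH− cells, and IRF7 at 30.7 ± 7.8 and 29.2 ± 5.21. CXCL10 stood at 15.2 ± 2.78 against 76 ± 76.2 RPKM and did not pass the test (limma, adjusted p = 0.948).

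Among 39 gene lists in the sham libraries camera called 12, 8 higher and 4 lower in ADEH+, and none with an estimated correlation (smallest adjusted p = 0.822) or with fry. No member of these lists passed over all genes. The called lists included glycolysis and hypoxia genes (median log2 difference 0.18; adjusted p = 0.000159), monocyte and macrophage markers (0.45; adjusted p = 0.00107) and matrix and tissue remodelling genes of macrophages (0.54; adjusted p = 0.00107), all higher in ADEH+. Type II interferon-responsive genes were lower (−0.31; adjusted p = 0.000784). Each of these 4 lists had an adjusted p of 0.822 with an estimated correlation. T cell markers differed by a median of −0.10 (camera, adjusted p = 0.00988; adjusted p = 0.822 with an estimated correlation). After sham ADEH− replicates 2, 4 and 6 stood apart in the mean log2 level of the type II interferon-responsive genes, at 4.90 to 5.66 against 3.04 to 3.71 in the other ADEH− and 3.60 to 4.20 in the ADEH+ libraries. Their monocyte and macrophage markers lay at 5.32 to 5.59 against 3.92 to 4.38 and 4.75 to 6.08, and their T cell markers at 5.78 to 6.10 against 6.23 to 6.42 and 5.76 to 6.19. Without these 3 donors the type II interferon-responsive genes differed by 0.43 after sham (exact permutation p = 0.0893). The donors were picked for their high level in this list, so a rise of its difference was set in advance. The monocyte and macrophage markers then differed by 1.05 (exact permutation p = 0.0357), against 0.41 with all donors (exact permutation p = 0.32). The same donors were the highest ADEH− libraries in these markers, so this shift follows from the choice as well.

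The fourth comparison asked how ADEH+ and ADEH− cells differed after HSV-1. In ADEH+ cells, some T cell markers and ribosomal protein genes were lower, and some monocyte and macrophage markers and type II interferon-responsive genes were higher. CD3E, a subunit of the T cell receptor complex, stood at 86.2 ± 9.41 RPKM (SD, n = 5) in ADEH+ and 145 ± 27.8 (SD, n = 6) in ADEH− cells. TCF7, a transcription factor of naive and memory T cells, stood at 42.8 ± 8.43 against 90.2 ± 27.5 RPKM. CXCL9, a chemokine induced by interferon gamma, stood at 661 ± 297 RPKM (SD, n = 5) in ADEH+ and 219 ± 189 (SD, n = 6) in ADEH− cells.

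Of 29 T cell markers 10 were lower in ADEH+ cells after HSV-1 and none higher, or 19 lower adjusted over the list alone, at a median log2 difference of −0.53 (camera, adjusted p = 1.19e-05; adjusted p = 0.522 with an estimated correlation). CD3E differed by −0.73 ± 0.13, the transcription factors TCF7 and LEF1 by −1.03 ± 0.22 and −0.83 ± 0.20, and the signalling adaptor LAT by −0.57 ± 0.14. Of 54 ribosomal protein genes 22 were lower, or 49 adjusted over the list alone, at a median of −0.37 (camera, adjusted p = 1.04e-12; adjusted p = 0.522 with an estimated correlation). RPL22 and RPL32 differed by −0.48 ± 0.10 and −0.50 ± 0.11. Of 27 monocyte and macrophage markers 4 were higher and 1 lower, or 6 higher and 1 lower adjusted over the list alone, at a median of 0.67 (camera, adjusted p = 0.000175; adjusted p = 0.522 with an estimated correlation). The higher members were the formyl peptide receptor FPR2 (1.96 ± 0.38), the beta-glucan receptor CLEC7A (1.95 ± 0.43), the sialic acid-binding receptor CD33 (1.51 ± 0.34) and CSF1R, the receptor for macrophage colony-stimulating factor (1.07 ± 0.30). The lower member was the adhesive glycoprotein THBS1 (−1.95 ± 0.57). Further genes with large differences were the immune receptors LILRA2 (2.13 ± 0.41) and SLAMF8 (2.06 ± 0.50), the transglutaminase TGM2 (2.31 ± 0.57), the cortisol-generating enzyme HSD11B1 (2.30 ± 0.63), the inflammatory caspase CASP5 (1.76 ± 0.49) and the myeloid transcription factor CEBPA (1.78 ± 0.51). Further genes lower in ADEH+ included ANKRD1 (−2.36 ± 0.47), the lysosomal fucosidase FUCA1 (−1.62 ± 0.35), LRRN3 (−1.61 ± 0.35) and GPA33 (−1.35 ± 0.22). All these genes passed limma's test at adjusted p-values of 0.0167 to 0.0479.

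Type II interferon-responsive genes were higher in ADEH+ cells after HSV-1 in 5 of 23 cases, or 12 adjusted over the list alone, at a median of 0.52 (camera, adjusted p = 1.19e-05; adjusted p = 0.522 with an estimated correlation). CXCL9 differed by 1.87 ± 0.54, the trafficking protein gene VAMP5 by 0.93 ± 0.21 and the tryptophanyl-tRNA synthetase gene WARS by 0.83 ± 0.22. IFNG differed by 2.65 ± 0.90, which did not pass (limma, adjusted p = 0.0702). MHC class II processing and presentation genes were higher in 3 of 14 cases, or 6 adjusted over the list alone (camera, adjusted p = 0.00315; adjusted p = 0.522 with an estimated correlation). The invariant chain CD74 differed by 0.72 ± 0.16, HLA-DRA by 1.47 ± 0.36 and the costimulatory ligand CD86 by 1.23 ± 0.27. Glycolysis and hypoxia genes were higher in 4 of 24 cases (camera, adjusted p = 0.0075; adjusted p = 0.522 with an estimated correlation), among them the lactate transporter SLC16A3 (1.07 ± 0.21) and GAPDH (0.37 ± 0.08). None of the 16 type I and III interferon genes passed over all genes, and all 16 were lower in ADEH+ adjusted over the list alone, at a median of −1.57 (camera, adjusted p = 4.34e-05; adjusted p = 0.563 with an estimated correlation). The smallest rise of a member with HSV-1 was 2.88 in ADEH+ and 4.38 in ADEH− cells. Some members can thus have met the deposited table's filter mainly through ADEH− libraries, so the count of 16 may lean to genes high in ADEH−. IFNB1 differed by −1.37 ± 0.45 (limma, adjusted p = 0.0668), IFNA2 by −1.46 ± 0.49 (limma, adjusted p = 0.0678) and IL29 by −1.37 ± 0.52 (limma, adjusted p = 0.0944). The type I interferon-stimulated genes as a list were not called (median −0.11; camera, adjusted p = 0.145), and 4 of 42 were lower, namely TRIM22 (−0.38 ± 0.09), DDX60 (−0.32 ± 0.08), SAMD9 (−0.31 ± 0.07) and IFI44L (−0.31 ± 0.09). CXCL10 (0.43 ± 0.31; limma, adjusted p = 0.35), IRF3 (−0.21 ± 0.10; limma, adjusted p = 0.149) and IRF7 (0.0040 ± 0.12; limma, adjusted p = 0.987) did not pass.

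After HSV-1, 995 of 8669 genes passed limma's test between the AD types, 383 higher and 612 lower in ADEH+, and 83 of them differed at least 2-fold, 69 up and 14 down. After TMM scaling 559 were higher and 377 lower. The count moved by over 1.5 times without ADEH+ replicate 1 (279), 2 (59) or 3 (650), and without ADEH− replicate 1 (196), 3 (12), 5 (17) or 6 (52), and was 1751 without ADEH− replicates 2, 4 and 6 together. Of the genes also tested after sham, 340 of 382 higher and 572 of 611 lower ones had the same sign there. Their median differences were 0.20 and −0.14 after sham, against 0.63 and −0.45 after HSV-1. The test of the response itself, given below, was passed by 7 of the 383 and 19 of the 612.

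**Figure D3:**
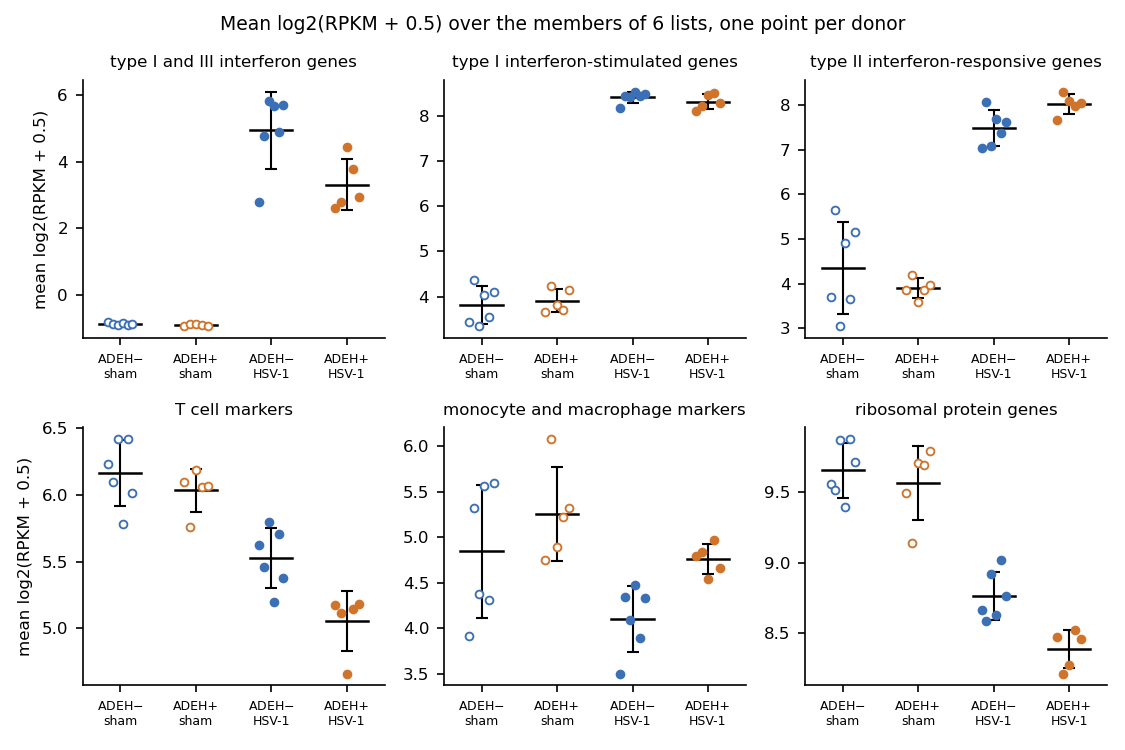
Mean log2(RPKM + 0.5) over the measured members of 6 gene lists, with 1 point per donor, open for sham and filled for HSV-1. Horizontal lines and bars are the mean ± SD of 6 ADEH− or 5 ADEH+ donors. After HSV-1 the T cell marker and ribosomal protein means differed by −0.47 and −0.37, ADEH+ minus ADEH− (exact permutation test, p = 0.0043 for both).

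Per donor, the mean of each list's members was also compared with a two-sided exact permutation test over the 462 splits of 11 donors, for 40 lists. After HSV-1 12 lists had p under 0.05, and 4 passed Benjamini-Hochberg adjustment over the lists. These were T cell markers (−0.47, ADEH+ minus ADEH−), ribosomal protein genes (−0.37), monocyte and macrophage markers (0.66) and glycolysis and hypoxia genes (0.17), each with an adjusted p of 0.0433 from the exact test. The monocyte and macrophage markers had also differed by 0.41 after sham, and their change differed by 0.25 (exact permutation p = 0.377), or by −0.12 (exact permutation p = 0.75) without ADEH− replicates 2, 4 and 6. The glycolysis and hypoxia genes had differed by 0.20 after sham (exact permutation p = 0.0519), and their change by −0.03 (exact permutation p = 0.779). The mean of the type I and III interferon genes differed by −1.64 (exact permutation p = 0.0325, adjusted p = 0.144). In the sham libraries 1 list had p under 0.05 (exact permutation p = 0.0498), and none passed adjustment.

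The fifth comparison asked whether the response to HSV-1 itself differed between the AD types. A small number of single genes passed this test, among them the PD-L1 gene CD274, which rose more in ADEH+ cells. CD274 rose by 5.46 in ADEH+ and 3.96 in ADEH− cells, a difference of 1.5 ± 0.21 (limma, adjusted p = 0.0394), and stood at 235 ± 84.4 RPKM (SD, n = 5) against 109 ± 44.9 (SD, n = 6) after HSV-1. FAM26F rose by 5.60 and 3.57, a difference of 2.03 ± 0.34, and ANKRD22 by 6.46 and 4.23, a difference of 2.23 ± 0.38. The chemokine receptor CXCR4 changed by −1.72 in ADEH+ and −1.0 in ADEH− cells, a difference of −0.72 ± 0.11. MXI1, an antagonist of MYC, changed by −1.74 and −0.91, a difference of −0.83 ± 0.10 (limma, adjusted p = 0.033).

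The response differed for 33 of 8705 genes at an adjusted p under 0.05, 8 with a positive and 25 with a negative difference, and 7 by at least 2-fold. The positive ones were APOL4 (3.82 ± 0.67), P2RY13 (2.15 ± 0.34), C16orf7 (1.15 ± 0.21), C4orf32 (1.02 ± 0.16) and the acetyl-CoA synthetase gene ACSS2 (0.73 ± 0.12) besides CD274, FAM26F and ANKRD22. Among the negative ones were CMTM8 (−0.96 ± 0.18), the polycomb gene CBX7 (−0.67 ± 0.10), the translation inhibitor PDCD4 (−0.62 ± 0.11) and the thyroid hormone receptor THRA (−0.56 ± 0.10). An unadjusted p under 0.05 was reached by 1888 genes, where 435 were the number for no difference at all.

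Of the 23 type II interferon-responsive genes 1 passed over all genes, ANKRD22, and 15 had a positive difference adjusted over the list alone, at a median difference of 0.81 (camera, adjusted p = 2.19e-14; adjusted p = 0.402 with an estimated correlation). The donors' means of this list differed by −0.45 after sham, 0.54 after HSV-1 and 0.99 in the response. The response differed by 0.42 (exact permutation p = 0.0714) without ADEH− replicates 2, 4 and 6, which stood high after sham. These donors were chosen by sham values that enter the response, so leaving them out is no separate test. CXCL9 differed by 2.60 ± 0.56 (limma, adjusted p = 0.0582) and IFNG by 2.91 ± 0.88 (limma, adjusted p = 0.106), and CXCL10 by 1.97 ± 0.58 (limma, adjusted p = 0.102). None of the 16 type I and III interferon genes passed over all genes, and all 16 had a negative difference adjusted over the list alone, at a median of −1.52 (camera, adjusted p = 3.22e-06; adjusted p = 0.565 with an estimated correlation). The filter may lean to genes high in ADEH− here as well. IFNB1 differed by −1.34 ± 0.48 (limma, adjusted p = 0.141). T cell markers had 1 member with a negative difference over all genes and 15 adjusted over the list alone, at a median of −0.40 (camera, adjusted p = 5.52e-06; adjusted p = 0.565 with an estimated correlation). Ribosomal protein genes had none over all genes and 35 adjusted over the list alone, at a median of −0.28 (camera, adjusted p = 6.16e-13; adjusted p = 0.565 with an estimated correlation). The 42 type I interferon-stimulated genes were not called (median −0.17; camera, adjusted p = 0.211). IRF3 (−0.21 ± 0.10) and IRF7 (−0.05 ± 0.18) did not pass. Over the donors' mean changes, 8 of 40 lists had an exact permutation p under 0.05, with T cell markers at −0.34 (p = 0.0043), or −0.21 without ADEH+ replicate 3 (p = 0.0095), and none passed adjustment (smallest adjusted p = 0.0866).

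The count of 33 depended on which donors were in the fit. It was 0 without ADEH+ replicate 1, without ADEH− replicate 1, 5 or 6 and without ADEH− replicates 2, 4 and 6 together, 1 without ADEH− replicate 4, 4 without ADEH− replicate 3, and 55, 69, 74, 77 and 115 without ADEH+ replicates 2, 3, 4 and 5 and ADEH− replicate 2. It was 0 without the donor block and with array weights, 10 after TMM scaling (7 positive, 3 negative), 17 with one median per library (10 positive, 7 negative) and 20 with quantile normalization (14 positive, 6 negative).

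**Figure D4:**
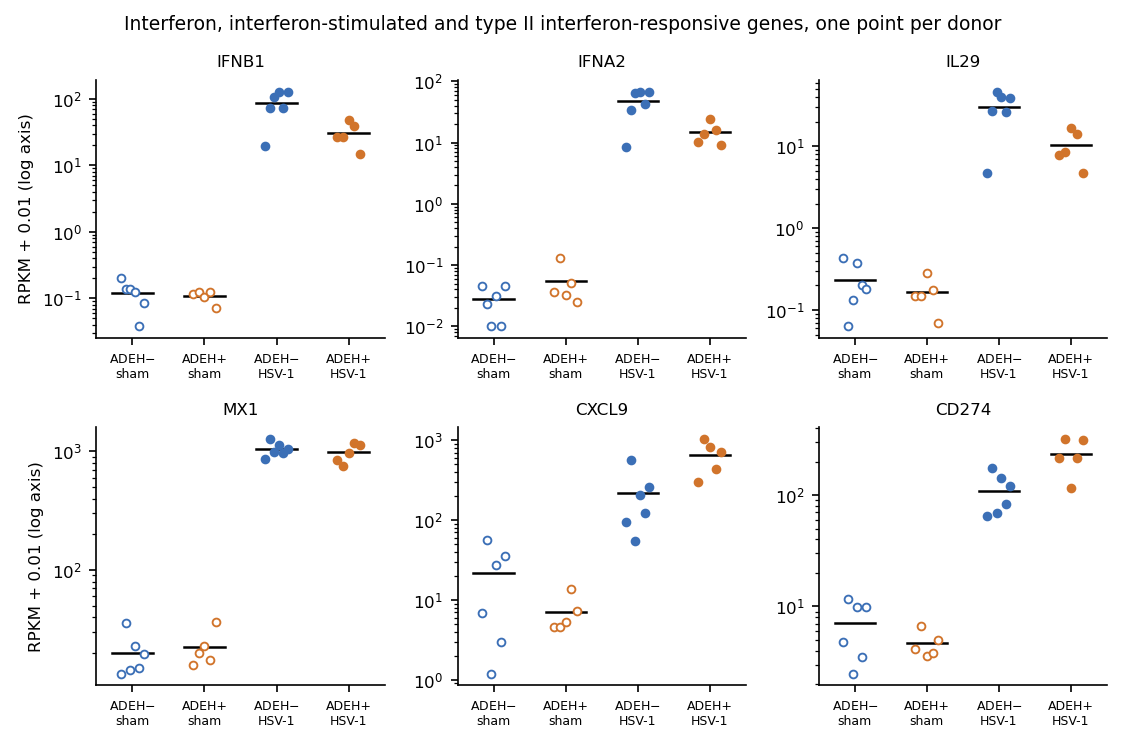
RPKM + 0.01 of 6 genes on a log axis, with 1 point per donor, open for sham and filled for HSV-1, and bars at the group means. After HSV-1 IFNB1 averaged 87.4 RPKM in ADEH− and 31 in ADEH+ donors, while CXCL9 averaged 219 and 661 and CD274 109 and 235.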

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

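Of the tests in this part, the following were chosen after the result was seen: the 3 tests of the interferon genes, for the T cell markers the change from sham to HSV-1 and the depth, and the tests with 1 donor or ADEH− replicates 2, 4 and 6 left out.

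A test of the difference itself set apart 33 genes whose response to HSV-1 differed between AD types (limma, adjusted p under 0.05), and in 100 splits of the 11 donors the highest other count was 5, so that only 1 split, the real one, gave as many. The count was 0 without ADEH+ replicate 1 or ADEH− replicate 1, 5 or 6, with array weights and without the donor block. It thus depended on the donors included and on the fit. The smallest adjusted p of all genes was 0.033 (limma), near the threshold. An unadjusted p under 0.05 was reached by 1888 genes, and by 1442 to 2100 with 1 donor left out (limma). The log2 differences (ADEH+ minus ADEH−) of the named genes among the 33 were 3.82 for APOL4, 2.23 for ANKRD22, 2.15 for P2RY13, 2.03 for FAM26F, 1.5 for CD274, 1.15 for C16orf7, 1.02 for C4orf32 and 0.73 for ACSS2. They were −0.96 for CMTM8, −0.83 for MXI1, −0.72 for CXCR4, −0.68 for ZNF395, −0.67 for CBX7, −0.66 for SNHG7, −0.65 for HIP1R and YPEL3, −0.64 for SSBP3, −0.62 for PDCD4, −0.58 for TMEM123 and −0.56 for THRA.

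Over the donors' mean changes, 8 of 40 lists had an unadjusted p under 0.05 in an exact permutation test of 5 against 6 donors, and none passed adjustment over the lists (adjusted p from 0.0866 to 0.184). By this exact permutation test these were erythroid markers (3 members, −0.63, p = 0.0022), T cell markers (−0.34, p = 0.0043), ribosomal protein genes (−0.28, p = 0.0065), type II interferon-responsive genes (0.99, p = 0.0173), chemokines (0.68, p = 0.026), B cell and plasma cell markers (−0.27, p = 0.0325), type I and III interferon genes (−1.60, p = 0.0346) and cell cycle and proliferation genes (−0.18, p = 0.0368). The chemokines and the type II interferon-responsive genes share members, CXCL9 among them, so the 8 lists are not independent.

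In 3 of 24 group scores (6 lists in 4 groups), 1 donor lay far below the others of the group, where chance gives about 1 in 20. The gap was 0.656 of the group's range for the type I and III interferon genes and 0.736 for the type I interferon-stimulated genes in ADEH− donors after HSV-1, and 0.876 for the T cell markers in ADEH+ donors after HSV-1. Both gaps in ADEH− donors belong to replicate 1, at 2.77 and 8.17. The 24 scores share donors, so the 3 flags are not independent and cannot be set against chance as a count.

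The first pattern is the lower level of T cell markers in ADEH+ cells after HSV-1. A smaller share of T cells from the start of culture is argued against as the whole cause by the widening of the difference. The mean marker difference was −0.13 after sham (exact permutation p = 0.357) and −0.47 after HSV-1. The donors' changes differed by −0.34 (exact permutation p = 0.0043, adjusted over the lists 0.0866), or by −0.21 without ADEH+ replicate 3 (p = 0.0095). Without ADEH− replicates 2, 4 and 6 the differences were −0.32 after sham and −0.65 after HSV-1. Both stood at the smallest p then possible (exact permutation p = 0.0179). That of the changes was then −0.33 (exact permutation p = 0.0893). These donors had the lowest T cell markers of the ADEH− sham libraries, so the wider sham difference follows from leaving them out. A larger share of RNA taken by induced transcripts is argued against as the whole cause, since 26 of 29 markers stayed lower after TMM scaling, at a median of −0.46 (SE 0.05). That SE is over the markers, which vary together, and not over donors. Fewer reads in ADEH+ is argued against by a mean depth that was 3.33 M reads higher. A greater loss or a changed state of T cells in infected cultures of ADEH+ donors may underlie the pattern, a hypothesis that stays open beside donor differences other than the history of eczema herpeticum.

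The second pattern is the lower level of type I and III interferon genes in ADEH+ cells after HSV-1, of which all 16 differed negatively and none passed over all genes (adjusted p = 0.563 for the list with an estimated correlation and 0.144 for the donors' means, whose unadjusted p was 0.0079 to 0.0667 with 1 donor left out and 0.179, at −1.19, without ADEH− replicates 2, 4 and 6). Whether fewer plasmacytoid dendritic cells, the main producers of interferon alpha in blood, took part cannot be decided from their markers after HSV-1. The median difference was 0.038 (SE 0.18 over 10 markers, 4 lower, with IRF7 also in another list). HSV-1 itself moved these markers, with 5 of 10 up and 2 down in ADEH− and 6 and 2 in ADEH+ cells. After sham the donors' means differed by 0.09 (exact permutation p = 0.649), with no sign of fewer such cells there. Reads shared among near-identical interferon alpha genes is argued against, because the summed level of 13 interferon alpha genes differed by −1.68 (unadjusted exact permutation p = 0.0325) and IFNB1, which has no such copy, by −1.37 (unadjusted exact permutation p = 0.0281). A weaker response of all interferon-related genes is argued against by the type II interferon-responsive genes, whose response was larger in ADEH+ by a median of 0.81 (mean over donors 0.99, exact permutation p = 0.0173, adjusted over the lists 0.173; mean 0.42 with p = 0.0714 without ADEH− replicates 2, 4 and 6), while a weaker type I response stays open, with −0.20 for the type I interferon-stimulated genes (p = 0.361; −0.50 with p = 0.0714 without these donors). Weaker interferon production per cell or an earlier end of it may remain, which a single sampling time of 21 h cannot part. Fewer plasmacytoid dendritic cells in the infected cultures stay open beside them. The filter of the deposited table may also favour interferon genes that are high in ADEH− cells.

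The third pattern is the fall of all 54 ribosomal protein genes after HSV-1 in both AD types. A larger share of RNA taken by induced transcripts is argued against as the whole cause, since the median stayed at −0.69 (SE 0.03) in ADEH− and −0.90 (SE 0.03) in ADEH+ cells after TMM scaling. Each SE is over the genes, which vary together, and not over donors. A loss of T cells, which carry many ribosomal transcripts, would lower them less than the T cell markers in every donor. They fell more in 10 of 11 donors (mean −1.02 against −0.79), in 10 after TMM scaling and in 6 after quantile normalization (mean −1.01 against −0.92). The marker mean cannot decide this, since single markers changed by −2.20 to 1.31 in ADEH− and −2.29 to 0.77 in ADEH+ cells. It includes markers that HSV-1 raised, 3 of 29 in ADEH− and 1 in ADEH+ cells. A loss of T cells therefore stays open. Degradation of host messenger RNA during infection or a shutdown of translation genes by interferon may take part, and neither was tested.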

How the results depend on the processing

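The median scaling was chosen after seeing the data, as were, for the lists, TMM, quantile normalization and the fit without the donor block, and for the donors' means of lists leaving out each donor, and leaving out ADEH− replicates 2, 4 and 6, whose sham libraries stood apart. The responses to HSV-1 were steady in number: over pseudocounts, filters, scalings, robust limma, array weights, fits of one AD type and the fit without the block, 5700 to 7217 genes changed in ADEH− and 5895 to 6656 in ADEH+ cells, and leaving out 1 donor gave 6145 to 6327 and 6382 to 6568. A fold change of at least 2 left 1485 and 2072 genes, 7 for the difference of responses and 83 between AD types after HSV-1, by its construction. The stricter filter changed nothing in the fits of 22 libraries, as every gene listed meets it, and is no test there.

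The 33 genes with a different response became 0 without the donor block, that is without the paired fit, 0 with array weights, 10 with TMM, 20 with quantile normalization, 17 with the median scaling and 0 to 115 when 1 donor was left out. The count was 0 without ADEH+ replicate 1 and without ADEH− replicates 1, 5 and 6, 4 without ADEH− replicate 3, 1 without ADEH− replicate 4, and 55, 69, 74 and 77 without ADEH+ replicates 2 to 5 and 115 without ADEH− replicate 2. Without ADEH− replicates 2, 4 and 6 together the 5 counts were 4894 (ADEH− response), 6412 (ADEH+ response), 0 (difference of responses), 1751 (AD types after HSV-1) and 0 (after sham), and the donors' responses differed by −0.33 in the T cell markers (exact permutation p = 0.0893) and −1.16 in the type I and III interferon genes (exact permutation p = 0.179). The cause was not tested.

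Between AD types after HSV-1, 857 to 1418 genes passed under the other pseudocounts, filters, scalings, tests and the fit with donors as a random effect. Leaving out 1 donor gave 12 to 1488, with 279, 59 and 650 without ADEH+ replicates 1 to 3, and 196, 12, 17 and 52 without ADEH− replicates 1, 3, 5 and 6; the cause was not tested. The replicate number as a block left 0 genes, and after sham 0 as well. These numbers name different subjects. Deviations of same-numbered libraries from their group means correlated at −0.137 to 0.294 after HSV-1 and −0.119 to 0.481 after sham. In these deviations 1 and 2 of 5 libraries correlated best with their own number. The sham comparison gave 0 genes in limma under each alternative run, leaving out 1 donor included.

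Of the gene lists, camera with an estimated correlation called 6 (ADEH− response), 5 (ADEH+ response), 0 (difference of responses), 0 (AD types after HSV-1) and 0 (after sham), in place of 21, 24, 17, 13 and 12. The estimated correlation lay above the preset 0.01 for 36 of 40 lists in the fits of 22 libraries and 38 of 39 in each comparison of AD types. Fry, which does not compare a list with other genes, called 37, 36, 0, 4 and 0. Quantile normalization called 11 lists for the difference of responses, 5 up and 6 down, in place of 12 up and 5 down. Without the paired fit 21, 23 and 16 lists were called in the 3 comparisons with a treatment term.

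Among 6130 alternative values of 175 genes followed, 5445 kept direction and side of the threshold, 592 kept direction and lost the call, 71 gained one and 22 reversed. Calls were lost mainly between AD types after HSV-1 (93 values, and 281 with 1 donor left out) and in the difference of responses (89 and 126), against 1 in the ADEH− and 2 in the ADEH+ response. All reversals were in genes with no call. IRF7 went from −0.051 to 0.0044 with TMM and 0.036 with array weights in the difference of responses, with −0.17 to 0.061 when 1 donor was left out. Between AD types after HSV-1 it went from 0.0040 to −0.038 with the replicate block and −0.043 with quantile normalization, with −0.067 to 0.085 over left-out donors, and CXCL10 went from 0.43 to −0.0088 with quantile normalization. After sham, leaving out 1 donor gave −0.062 to 0.048 for IRF3 and −0.062 to 0.13 for IRF7. The cause was not tested. Genes below 5 RPKM in nearly all libraries are outside the deposited table, and changes of log2 0.5 between AD types were recovered in 47.8% of simulated genes after HSV-1, so smaller differences can be missed.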

Other observations

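The splits that part every donor's pair were chosen after the data were examined, and the other tests of splits in this part before. HSV-1 also raised most heat shock and cell stress genes and some metallothionein genes in both AD types. Heat shock and cell stress genes rose in 13 of 18 cases and fell in 2 in ADEH− cells (median log2 change 0.55; camera, adjusted p = 1.05e-05; adjusted p = 0.0149 with an estimated correlation), and rose in 13 and fell in 3 in ADEH+ cells (0.62; camera, adjusted p = 0.000108; adjusted p = 0.0186 with an estimated correlation). The co-chaperone DNAJA1 rose by 1.8 ± 0.08 (SE) and 1.87 ± 0.08, and the constitutive chaperone HSPA8 by 1.12 ± 0.06 and 1.18 ± 0.06. Of 7 metallothionein genes, which bind zinc and copper, 5 rose in ADEH− and 4 in ADEH+ cells and none fell (camera, adjusted p = 0.00133 and 0.0102; adjusted p = 0.261 and 0.346 with an estimated correlation). MT2A reached 747 ± 146 RPKM (SD, n = 6) in ADEH− and 641 ± 279 (SD, n = 5) in ADEH+ cells, from 48.6 ± 22.1 and 58.8 ± 42.6 after sham. Immediate early genes rose in 13 of 19 cases and fell in 3 in ADEH− cells (camera, adjusted p = 0.000159; adjusted p = 0.0327 with an estimated correlation), and rose in 11 and fell in 4 in ADEH+ cells (camera, adjusted p = 0.00166; adjusted p = 0.0717 with an estimated correlation). Eicosanoid genes fell in 6 of 11 cases and rose in 4 in both AD types, and camera did not call the list (adjusted p = 0.785 and 0.934). The thromboxane synthase TBXAS1 changed by −3.5 ± 0.20 in ADEH− and −3.61 ± 0.22 in ADEH+ cells, and the leukotriene B4 receptor LTB4R by −1.42 ± 0.09 and −1.58 ± 0.10.

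Other cell type markers moved in both directions. B cell and plasma cell markers rose in 7 and fell in 8 of 22 cases in ADEH− cells and rose in 3 and fell in 10 in ADEH+ cells, and camera called neither (adjusted p = 0.313 and 0.934). The B cell kinase BLK changed by −1.02 ± 0.08 and −1.44 ± 0.08 and the B cell receptor subunit CD79B by −1.02 ± 0.11 and −1.41 ± 0.12, while the adaptor BLNK rose by 1.12 ± 0.09 and 1.17 ± 0.10. Plasmacytoid dendritic cell markers rose in 5 of 10 cases in ADEH− and 6 in ADEH+ cells and fell in 2 in each (camera, adjusted p = 0.0221 and 0.0212; adjusted p = 0.0961 and 0.109 with an estimated correlation). Basophil, eosinophil and mast cell markers fell in 5 of 6 cases in ADEH− and 6 of 6 in ADEH+ cells and camera did not call them (adjusted p = 0.236 and 0.143). The 3 erythroid markers fell in both, at medians of −0.41 and −1.03, and HBA1, a hemoglobin gene, stood at 25.1 ± 31.4 RPKM in ADEH− and 23.9 ± 16.3 in ADEH+ cells after sham.

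The counts of changed genes were set beside other splits of the same samples into groups of the same sizes, drawn 100 times with the real split included. In ADEH− donors the real split gave 6494 genes and the highest other 5499, and in ADEH+ donors 6656 and 5243. These splits mix the libraries of donors, although each donor gave a pair, and the high ones keep most libraries with their treatment. Among the 32 splits that part every pair of the ADEH− donors the highest other count was 0. Only the real split gave as many, a share of 1 in 32 that makes chance unlikely without excluding it. In ADEH+ donors 16 splits part every pair, too few for a share under 0.05, with a real count of 6656 and a highest other count of 19. Between AD types after HSV-1 the real split gave 995 genes and the highest other 789. Only the real split of the 100 drawn, from 462 possible, gave as many. That share makes chance unlikely without excluding it, and the count fell to 12 without ADEH− replicate 3. After sham the real split gave 0 genes (limma; 321 genes at an unadjusted p under 0.05) and the highest other 1, and since each of 100 splits gives at least 0 genes, the count of splits decides nothing there.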
